A study of Mus musculus with 6 samples.

How the data were processed

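RNA was measured in primary enamel organ cells from the lower incisors of C57BL/6 mice, in 3 libraries from Stim1/2 knockout mice (DKO, replicates 1, 3 and 4) and 3 from wild-type mice (WT, replicates 1, 2 and 3). The enamel organ is the epithelial tissue that holds the ameloblasts, the cells that deposit and then mature the enamel. Per the labels' protocols, cells were lysed directly after isolation, 500 ng of DNase-treated total RNA entered a TruSeq RNA v2 preparation with 12 PCR cycles, and the libraries were read as paired ends of 150 nt on an Illumina HiSeq. This kit does not mark the strand of a transcript.

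The deposited gene counts are whole numbers per Ensembl gene, not normalised, from 1 table per library. The deposited FPKM values (fragments per kilobase of transcript, scaled to the library's fragments) are Cufflinks gene tables, per the file headers. GRCm38, Trimmomatic 0.32, Cufflinks 2.2 and HTSeq are named, per the submitters' processing notes, without a role or an order. The aligner, the annotation release and the counting settings are not given in the sources used here. The count tables held 46603 genes, with 0 rows that named no gene. The FPKM tables paired 46406 of these with a symbol, and an Ensembl symbol table named a further 192. Biotypes, positions and transcript lengths came from GENCODE vM21 on GRCm38, which covered 46091 of the genes and may not be the release the authors used. Its positions are 1-based.

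Total counts ran from 18609759 to 22829411 per library, so counting error was small for all but the rarest genes, and the 3 libraries per group set the precision. Fragments without molecular identifiers are not independent molecules. The labels do not say that the replicates came from separate animals. Each group held libraries of both sexes, so not all of a group's libraries came from 1 animal, but p-values measure only the spread between these samples. A Pearson correlation of log2 counts per 1e6 (CPM) between libraries of a group lay between 0.980 and 0.984, and no pair of libraries agreed within sampling noise, with a chi-square per degree of freedom of at least 14.1.

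DKO was compared with WT by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the filterByExpr filter and no covariate. Genes with a Benjamini-Hochberg adjusted p below 0.05 over the 14721 tested genes are called. A standard error of a log2 fold change is its size over the square root of the test's F value. Stim1 and Stim2 also got an exact permutation test. Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, adjusted over 30 lists, with camera at an estimated correlation and fry beside it. The lists were store-operated calcium entry, calcium pumps and binding proteins, enamel matrix, maturation-stage ameloblast, iron handling, mitochondrially encoded and nuclear-encoded respiratory chain, mitochondrial calcium uptake and dynamics, glutathione and antioxidant enzymes, endoplasmic reticulum stress, lysosome, junctions, calcineurin and NFAT, immediate early genes, proliferation, glycolysis and sterol synthesis, plus markers of dental epithelium, stratum intermedium, oral keratinocytes, mesenchyme, odontoblasts and osteoblasts, endothelium, leukocytes, neutrophils, osteoclasts, erythroid cells, skeletal muscle, nerve and cartilage.

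The design, the lists and the rule for named genes were fixed before the data were examined. The rule names Stim1 and Stim2. It adds the 8 largest rises and the 8 largest falls among called protein-coding genes with a symbol, a mean of at least 50 counts and no overlap between the groups. It adds up to 4 called members of each list by adjusted p. It also names Amelx, Ambn, Enam, Mmp20, Klk4, Odam, Amtn, Orai1, Orai2, Orai3, Itpr1, Itpr2, Itpr3 and Atp2a2 whether or not they passed. Of the genes the rule names, 1 is not reported here. Other genes that are named were chosen after their values were seen, and the text says so.

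Alternatives were DESeq2 size factors, total counts, upper-quartile scaling, TMM without the 50 most abundant genes, no low-count filter, a mean of at least 50 counts, the replicate number as a block, each library left out in turn, the DESeq2 1.42.0 Wald test, and limma with a trend on log2(FPKM + 1) or log2(FPKM + 0.1). The FPKM tests kept genes at 1 or more in at least 3 libraries, or all genes above 0. They left out 9 genes with a failed FPKM estimate, among them Ambn and Amelx, which are listed at 0 in some libraries. Added after seeing the data were a term for libraries with Xist above 100 CPM, offsets for transcript length and GC content from a lowess fit per library with a span of 0.3, and a fit without oral keratinocyte and muscle genes.

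The tests were run first on simulated counts for the same genes and depths, with 200 genes changed in the DKO libraries. The changed genes were drawn from those with a mean of at least 50 counts. Each gene's spread between libraries was set by its abundance alone, so recovery may be lower for rarer genes and for real genes that vary more. Over 14531 simulated genes, edgeR recovered 98.5% of the genes changed 4-fold, 79.1% of those changed 2-fold and 55.2% of those changed 1.5-fold, with 7.74% false calls. DESeq2 recovered 98.5%, 83.6% and 55.2% over 14435 genes with 14.6% false calls, and limma on FPKM recovered 100%, 78.1% and 33.8% over 12830 genes with 8% false calls. With no gene changed, edgeR called 0 genes. The length offset brought a simulated length trend from a Spearman rho of 0.77 to 0.02.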

Results

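The data were gene counts of 6 libraries of lower-incisor enamel organ cells, 3 from Stim1/2 knockout mice (DKO) and 3 from wild-type mice (WT). STIM1 and STIM2 are calcium sensors of the endoplasmic reticulum that open the ORAI channels of the plasma membrane when the store empties, a route called store-operated calcium entry. The libraries held 19563883, 21196538 and 18609759 counts for DKO replicates 1, 3 and 4, and 22829411, 21127654 and 22053485 counts for WT replicates 1, 2 and 3. The enamel matrix genes Ambn and Amelx were the most abundant transcripts, and the top 2 genes took from 6.86% of the counts in WT 1 to 15.8% in DKO 3. The first principal component held 38.3% of the variance and had all DKO libraries on one side and all WT libraries on the other. Levels are given in normalised counts per 1e6 (CPM, TMM-scaled). Xist was at 488, 810 and 913 CPM in DKO 1, WT 1 and WT 2 and at most 1.22 CPM in DKO 3, DKO 4 and WT 3, which expressed the Y-linked genes, so both groups mixed the sexes. The mix was unequal, so sex was partly confounded with genotype.

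The question the series title poses is what store-operated calcium entry does for ameloblasts, and the first comparison was of the targeted genes themselves. Stim1 (ENSMUSG00000030987, GRCm38 chromosome 7, 102267806 to 102437319, plus strand) stood at 422 ± 65.1 CPM in WT and 125 ± 18.1 CPM in DKO (SD, n = 3 each). DKO thus kept 29.6% of the WT level, a log2 fold change of -1.75 (SE 0.15, edgeR adjusted p = 0.00553). Stim2 (ENSMUSG00000039156, chromosome 5, 53998499 to 54121057, plus strand) stood at 261 ± 42.6 CPM in WT and 122 ± 15.8 CPM in DKO (SD, n = 3 each), or 46.8% of WT. Its log2 fold change was -1.10 (SE 0.14, edgeR adjusted p = 0.018). The highest DKO library lay below the lowest WT library for both genes, at 143 against 362 CPM for Stim1 and at 136 against 229 CPM for Stim2. The exact two-sided permutation p was 0.1 for each gene, the smallest that 3 against 3 libraries allow. These are counts over whole genes, so they include any exons outside the deleted part. The call of Stim2 ended without DKO 1, DKO 3, DKO 4 or WT 3 (adjusted p from 0.0574 to 0.0987) and with a term for the Xist-high libraries (0.0557), and over all alternatives its adjusted p ran from 2.42e-10 to 0.126.

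**Figure D1:**
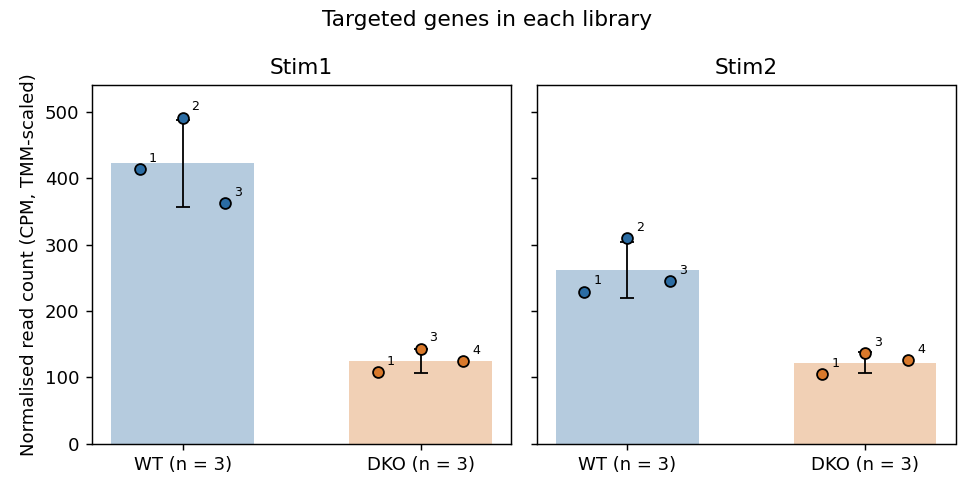
Normalised read counts (CPM, TMM-scaled, vertical axis) of Stim1 and Stim2 in the WT and DKO libraries; bars are group means, error bars SD, points the libraries with their replicate numbers. Each DKO library lies below each WT library, with Stim1 at 125 CPM in DKO on average against 422 CPM in WT.

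Across the transcriptome, the next comparison asked which genes differ between DKO and WT enamel organs. The 4 genes with the largest rises stood at or below 1.11 CPM in WT. Tmem179 (ENSMUSG00000054013, chromosome 12, 112500189 to 112516747, minus strand), which encodes a membrane protein, went from 0.623 ± 0.291 to 20.9 ± 9.55 CPM (SD, n = 3 each), 33.6-fold higher in DKO, and Qrfp, a neuropeptide precursor, from 0.248 to 7.79 CPM, 30.2-fold higher (log2 fold change 5.58 without WT 3). Has1 (ENSMUSG00000003665, chromosome 17, 17843323 to 17855205, minus strand), a hyaluronan synthase, rose 18.1-fold from 0.695 ± 0.0992 to 12.8 ± 1.81 CPM, and Tph1 (ENSMUSG00000040046, chromosome 7, 46644641 to 46672537, minus strand), the enzyme that limits serotonin synthesis outside the brain, rose 17.4-fold from 1.11 ± 0.175 to 19.5 ± 2.38 CPM (SD, n = 3 each). The log2 fold changes of these 4 genes were 5.07 (SE 0.44), 4.92 (SE 0.48), 4.18 (SE 0.20) and 4.12 (SE 0.18), with edgeR adjusted p of 0.00553, 0.00843, 0.000328 and 0.000308. The neuronal adhesion gene Nrxn2 rose from 0.725 ± 0.298 to 11.2 ± 1.46 CPM and the secreted matrix protein gene Ccdc80 from 14.8 ± 4.51 to 119 ± 17.4 CPM (SD, n = 3 each), the transporter gene Abca13 7.78-fold and the guanylate cyclase receptor gene Gucy2c 6.93-fold. The call of Gucy2c ended without DKO 3, DKO 4, WT 1 or WT 3 (adjusted p from 0.0633 to 0.0869), and those of the other 7 genes held whichever library was left out.

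Among the largest falls, Dynap (ENSMUSG00000024512, chromosome 18, 70240429 to 70244582, minus strand) stood at 24.1 ± 16.4 CPM in WT and 0.659 ± 0.487 CPM in DKO (SD, n = 3 each), 36.5-fold lower, with a log2 fold change of -5.19 (SE 0.85, edgeR adjusted p = 0.0432; -5.79 without DKO 4). Kcnmb2, an auxiliary subunit of calcium-activated potassium channels, was 8.07-fold lower and Bglap2, an osteocalcin gene, 6.73-fold lower. Bglap2 has a near-identical neighbour, Bglap, named here after its value was seen, which stood at 11.5 CPM in WT and 3.26 in DKO and did not pass (edgeR adjusted p = 0.192), so how reads were divided between them is uncertain. The keratin gene Krt6a fell 3.86-fold from 328 ± 94.1 to 84.9 ± 24.0 CPM (SD, n = 3 each), while its paralog Krt6b, named after its value was seen, had a log2 fold change of -2.20 and did not pass (adjusted p = 0.124). After Stim1, the falls continued with Tmem63c (3.35-fold), the adenosine receptor gene Adora2b (3.23-fold) and Syne2, a linker of nucleus and cytoskeleton (2.21-fold). Of these falls, Stim1 and Bglap2 passed whichever library was left out. The calls of Dynap, Kcnmb2 and Tmem63c ended without any 1 library but WT 2 (adjusted p from 0.0638 to 0.170). Dynap also missed the threshold with a term for the Xist-high libraries (edgeR adjusted p = 0.0787). That of Adora2b ended without DKO 1, DKO 3, DKO 4 or WT 1 (0.0539 to 0.112), and those of Krt6a and Syne2 without DKO 3, DKO 4 or WT 3 (0.0577 to 0.114).

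In total edgeR called 153 of 14721 genes, 108 higher and 45 lower in DKO, and 87 of them by at least 2-fold, 70 higher and 17 lower. All 153 had the 3 DKO libraries on one side of the 3 WT libraries, as did 23.3% of all tested genes, where chance gives 10%. The count was sensitive to single libraries: it was 335 without WT 2, 102 without DKO 1, 84 without WT 1, 30 without WT 3, 23 without DKO 3 and 21 without DKO 4. The larger direction turned with WT 2: without that library 124 genes were higher and 211 lower. The count was 71 with the Xist-high libraries as a term, 554 (312 higher, 242 lower) without a low-count filter, 826 by the DESeq2 Wald test and 77 by limma on FPKM.

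**Figure D2:**
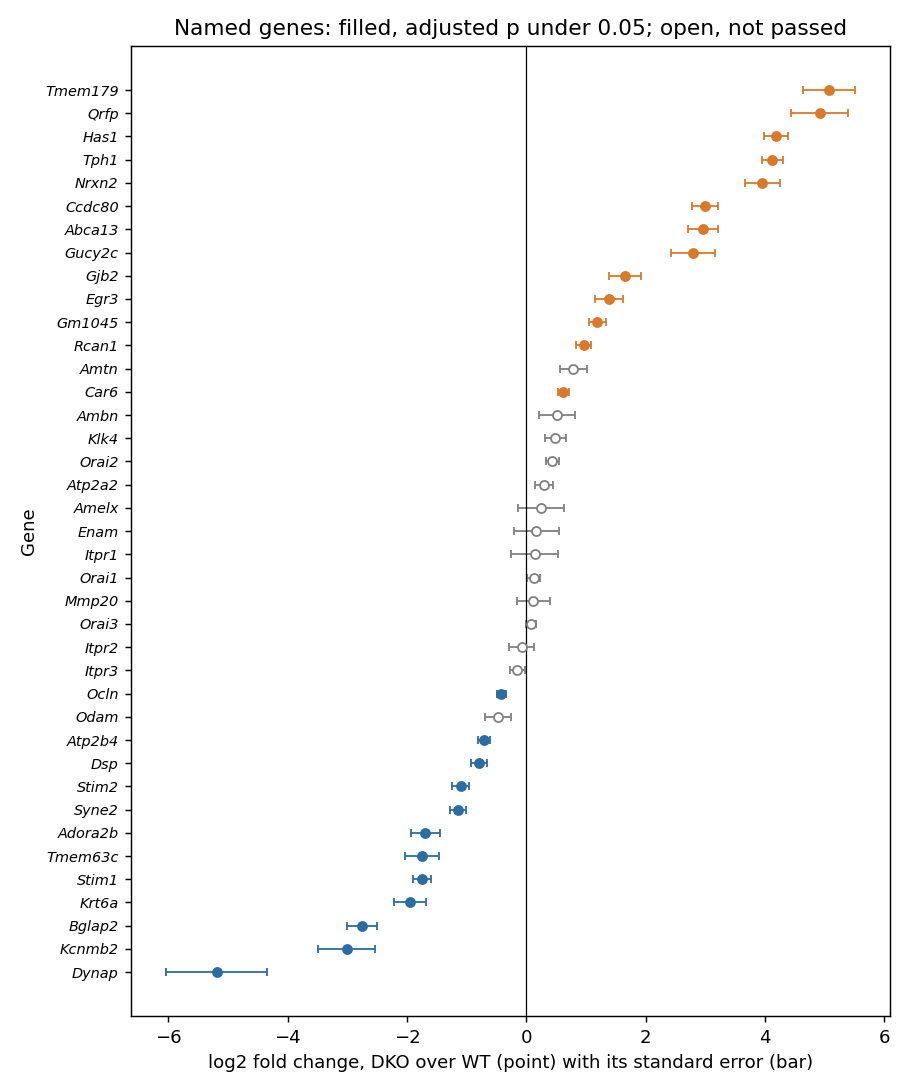
log2 fold change of DKO over WT (horizontal axis, point) with its standard error (bar) for genes named by the fixed rule, 3 libraries per group; filled points have an edgeR adjusted p below 0.05 and open points do not. The points run from -5.19 for Dynap to 5.07 for Tmem179, and the enamel matrix genes Amelx, Ambn, Enam and Mmp20 lie among the open points.

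None of the main enamel matrix genes passed the edgeR test. Ambn stood at 51246 ± 14774 CPM in WT and 73354 ± 14704 in DKO, Amelx at 48665 ± 17901 and 57654 ± 20425, and Enam at 5860 ± 2474 and 6584 ± 2535 (SD, n = 3 each), with log2 fold changes of 0.52 (SE 0.30), 0.24 (SE 0.38) and 0.17 (SE 0.38). The enamel protease genes also missed the threshold, with Mmp20, of the secretory stage, at 0.12 (SE 0.28, edgeR adjusted p = 0.865) and Klk4, of the maturation stage, at 0.49 (SE 0.17, adjusted p = 0.208). Of the 20 tested enamel matrix and secretory-stage genes 0 rose, over all genes and adjusted over the list alone.

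Of the 24 tested maturation-stage genes, 2 rose and 22 did not pass. Gm1045, also known as Odaph, a gene needed for enamel mineralisation, rose 2.29-fold from 42.3 ± 7.48 to 96.6 ± 9.26 CPM, and the carbonic anhydrase gene Car6 rose 1.54-fold from 370 ± 26.1 to 568 ± 24.4 CPM (SD, n = 3 each). The call of Gm1045 ended without DKO 3 or DKO 4 (adjusted p from 0.0627 to 0.0783) and that of Car6 without any 1 library but WT 2 (0.0719 to 0.150). With a term for the Xist-high libraries 1 member of the list passed. Amtn had a log2 fold change of 0.78 (SE 0.23, edgeR adjusted p = 0.146, and 0.04995 without WT 2, where it passed) and Odam of -0.47 (SE 0.21, adjusted p = 0.294). Adjusted over the list alone, 6 rose and 3 fell. The 3 that fell there, named after their values were seen, were Gm17660 (385 CPM in WT, 79.2 in DKO), the anion exchanger gene Slc26a4 (17.5 in WT, at most 2.03 in a DKO library) and Wdr72 (261 and 181). Camera placed the list higher in DKO (adjusted p = 0.0014, 0.533 with an estimated correlation), with a median log2 fold change of 0.23, or 0.12 without DKO 3, and a mean of 0.01.

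In the store-operated calcium entry list, Stim1 and Stim2 were the 2 of 16 members that fell, and 0 rose. Adjusted over the list alone, 2 rose and 2 fell. The channel genes Orai1, Orai2 and Orai3 had log2 fold changes of 0.13 (SE 0.11), 0.44 (SE 0.11) and 0.08 (SE 0.08), and the IP3 receptor genes Itpr1, Itpr2 and Itpr3 of 0.14 (SE 0.39), -0.08 (SE 0.21) and -0.15 (SE 0.12), none of which passed the edgeR test. Orai2 passed by DESeq2 (adjusted p = 0.00659, from there to 0.377 over all alternatives), as did Amtn (0.001, from there to 0.708). Of 25 calcium pumps, exchangers and binding proteins 1 fell, the plasma membrane pump gene Atp2b4, from 205 ± 20.3 to 125 ± 12.9 CPM (SD, n = 3 each; edgeR adjusted p = 0.033), while the store pump gene Atp2a2 had a log2 fold change of 0.29 (SE 0.15, adjusted p = 0.359). Of 23 calcineurin and NFAT genes 1 rose: Rcan1, an inhibitor of calcineurin that NFAT itself induces, went from 1072 ± 57.6 to 2084 ± 205 CPM (SD, n = 3 each), 1.94-fold higher (edgeR adjusted p = 0.0179). Of 21 immediate early genes 1 rose, Egr3, from 1.46 to 3.85 CPM. The call of Atp2b4 ended without any 1 library but WT 2 (adjusted p from 0.0574 to 0.133), that of Rcan1 without DKO 3, DKO 4 or WT 3 (0.0691 to 0.113) and that of Egr3 without any 1 library (0.0575 to 0.170). With a term for the Xist-high libraries 0 calcium pump and 0 immediate early genes passed, so the calls of Atp2b4 and Egr3 ended there too. Adjusted over the list alone, 1 calcium pump gene rose and 1 fell, 1 NFAT gene rose and 2 fell, and 4 immediate early genes rose and 1 fell. None of these 3 lists, nor store-operated entry, was called by camera (adjusted p from 0.116 to 0.504), but the calcium pump list was called without WT 2 (0.0158) and the immediate early list without WT 1 (0.0249).

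Lower in DKO by camera at its preset correlation were 4 lists of epithelial genes, none of which was called with an estimated correlation (adjusted p = 0.283, 0.313, 0.313 and 0.318 in the order given here). Of 13 dental epithelium markers 12 had a negative log2 fold change, with a median of -0.47. Adjusted over the list alone 6 members fell, among them Krt5 (4339 CPM in WT, 2992 in DKO) and Krt14 (4084 and 2956), named after their values were seen. Of 9 oral keratinocyte genes Krt6a fell, 6 fell adjusted over the list alone, and the median was -1.52. Of 30 junction genes 2 fell, the desmosome gene Dsp from 1305 ± 194 to 755 ± 19.5 CPM (SD, n = 3 each) and the tight junction gene Ocln from 48.5 to 36.3 CPM, and 5 fell adjusted over the list alone. Of 12 stratum intermedium and papillary layer genes, the gap junction gene Gjb2 rose 3.15-fold, against the direction of its list, and 7 fell adjusted over the list alone. The calls of Dsp and Ocln ended without any 1 library but WT 2 (adjusted p from 0.0641 to 0.184), that of Gjb2 without DKO 3, DKO 4, WT 1 or WT 3 (0.0691 to 0.152) and that of Krt6a without DKO 3, DKO 4 or WT 3 (0.0770 to 0.114). With a term for the Xist-high libraries 0 junction genes passed, so the calls of Dsp and Ocln ended there too. Camera no longer called the stratum intermedium list without DKO 1, WT 2 or WT 3 (0.0510 to 0.1001). Camera adjusted p were 6.61e-05, 2.32e-06, 0.000977 and 0.0132 for these 4 lists at the preset correlation. Fry, which asks whether a list's genes move one way on balance, called the dental epithelium list alone (adjusted p = 0.0162).

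Higher in DKO by camera, beside the maturation-stage list, were 8 lists in which no member passed over all genes, and none of the 8 was called with an estimated correlation (adjusted p from 0.322 to 0.794). Proliferation genes had 29 of 31 members above 0 with a median log2 fold change of 0.65, and 11 rose adjusted over the list alone, among them Top2a (8.69 CPM in WT, 15.7 in DKO) and Mcm5 (7.48 and 13.9), named after their values were seen. The 2 members most abundant in WT, also named after their values were seen, barely differed: Pcna (50.9 CPM in WT, 51.7 in DKO) and Rrm1 (45.9 and 44.9). The median was 0.44 without DKO 1 and 0.45 over the 24 members with a mean of at least 50 counts. Of the markers of cells outside the epithelium, 16 of 16 leukocyte markers lay above 0 with a median of 0.44, 12 of 12 endothelium markers with a median of 0.41, and 14 of 15 mesenchyme markers with a median of 0.32. The mesenchyme median was 0.19 without DKO 1 and 0.12 without WT 2, and camera then did not call the list (adjusted p = 0.166 and 0.441). Adjusted over the list alone, 4 leukocyte markers, 5 endothelium markers and 0 mesenchyme markers rose. Nuclear-encoded respiratory chain genes lay above 0 in 72 of 76 cases, but with a median of only 0.09. The medians were 0.17 over 33 endoplasmic reticulum stress genes and 0.09 over 39 lysosome genes, and adjusted over the list alone 0 members of these 3 lists rose. Of 3 tested cartilage genes, all at or below 2.32 CPM on average, 2 rose adjusted over the list alone. Camera adjusted p ran from 3.37e-08 for proliferation to 0.0227 for lysosome over these 8 lists. Calls also ended for the respiratory chain without DKO 4 or WT 1 (medians 0.05 each), endoplasmic reticulum stress without DKO 1 or WT 3, lysosome without DKO 4, WT 2 or WT 3 (medians from 0.06 to 0.08) and cartilage without DKO 1, WT 1 or WT 2 (medians from 0.70 to 0.72), with adjusted p from 0.0523 to 0.218. The respiratory chain median was 0.17 without WT 2 and the cartilage median 0.98 without DKO 3, and both lists were called. Each of these cartilage fits tested 4 members, not 3, so their medians are not over the same genes as the 1.72 with all libraries.

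The remaining 13 lists were not called (camera adjusted p from 0.119 to 0.637): enamel matrix, iron handling, mitochondrially encoded respiratory chain, mitochondrial calcium uptake and dynamics, glutathione and antioxidant enzymes, glycolysis, sterol synthesis, odontoblast and osteoblast, neutrophil, osteoclast, erythroid, skeletal muscle, and nerve. Bglap2 was the one called gene among the odontoblast and osteoblast markers, and 0 members of the iron, respiratory chain, mitochondrial, glutathione, glycolysis, sterol, neutrophil, osteoclast, erythroid, muscle and nerve lists passed over all genes. Adjusted over the list alone, 2 odontoblast and osteoblast markers rose and 2 fell, 2 nerve markers rose and 1 fell, 1 iron gene fell, and 0 members of the respiratory chain, mitochondrial, glutathione, glycolysis, sterol, neutrophil, osteoclast, erythroid and muscle lists passed. Neutrophil (0 of 10), erythroid (0 of 6) and skeletal muscle markers (2 of 14) were seldom above 0, unlike those of leukocytes and endothelium, with medians of -1.16, -0.30 and -0.90. These rested on single libraries: the neutrophil median was -0.27 without WT 2, the erythroid median 0.004 without DKO 1, 0.06 without WT 3 and -0.75 without DKO 4, and the muscle median -0.38 without DKO 4 and 0.25 without WT 3. Camera called the neutrophil, erythroid and muscle lists lower without WT 1 (adjusted p = 9.45e-11, 0.00168 and 0.00102), with medians of -1.72, -0.65 and -1.33, and muscle also without DKO 1 (0.0134, median -1.39). The erythroid fits without DKO 1, DKO 4 or WT 1 tested 7 members, not 6, so their medians are not over the same genes. Without WT 3 it called the osteoclast (0.0355) and sterol (0.0122) lists. Median and mean differed in sign in the store-operated entry, odontoblast and osteoblast, glutathione, immediate early and sterol synthesis lists. In all, camera called 13 of 30 lists, 9 higher and 4 lower. With an estimated correlation camera called 0, with 4 at an unadjusted p below 0.05, and fry called 1, with 9 at an unadjusted p below 0.05. One other split of the 6 libraries into 3 and 3 also gave 13 camera calls, and the remaining splits gave from 6 to 12. The number of lists called at the preset correlation thus does not set the genotype split apart.

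**Figure D3:**
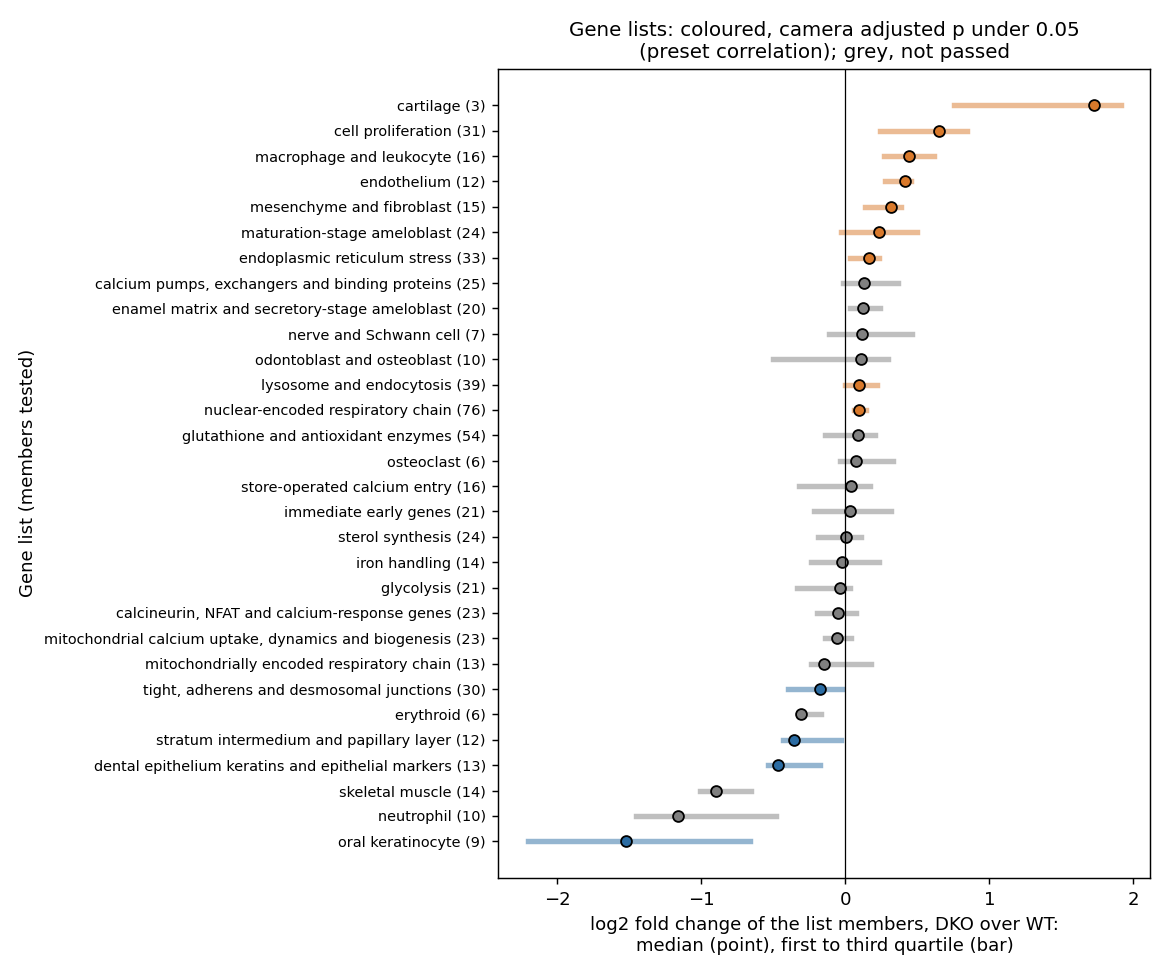
Median log2 fold change of DKO over WT (horizontal axis, point) and interquartile range (bar) of the tested members of each gene list, with the number of members in brackets; coloured lists have a camera adjusted p below 0.05 at the preset correlation, orange higher and blue lower in DKO, and grey lists do not. The medians run from -1.52 for oral keratinocyte genes to 1.72 for the 3 cartilage genes.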

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

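The Xist term, the length and GC offsets and the fit without keratinocyte and muscle genes were chosen after seeing the data. In each setting the genes of the 153 calls that were tested kept their sign. That says little, since in all 153 the groups did not overlap. The balance of calls turned from 70.6% higher to 37% without WT 2 and 40.2% with the replicate block. Medians of some lists that were not called also changed sign, such as skeletal muscle from -0.90 to 0.25 without WT 3 and odontoblast and osteoblast from 0.11 to -0.39 without DKO 1. Counts of genes changed, higher, lower and changed at least 2-fold were 554, 312, 242 and 230 without a low-count filter, where 25264 genes were tested. They were 826, 469, 357 and 259 by the DESeq2 Wald test, which holds all 153 calls, and 71, 52, 19 and 54 with the Xist-high libraries as a term. By limma they were 77, 61, 16 and 47 on log2(FPKM + 1), 77, 60, 17 and 54 on log2(FPKM + 0.1), and 11, 8, 3 and 7 on log2(FPKM + 1) without a filter. A mean of at least 50 counts left 29 lower calls. The cause was not tested for these. Replicate numbers 1 and 3 occur in both groups but no label says what a number shares. Deviations correlated at 0.19 for number 1 and at 0.0001 for number 3, and as high between unlike numbers (DKO 3 with WT 2 0.19, DKO 4 with WT 3 0.20), so the numbers are not taken to pair the libraries. With the replicate block 328 genes changed, 132 higher and 196 lower, 208 by at least 2-fold, and 8 lists were called. That block leaves DKO 4 and WT 2 out of the contrast, which then rests on replicates 1 and 3 of each group. It also leaves almost no residual degrees of freedom to estimate the spread, so its count of calls is a weak guide. Without WT 2 alone 335 genes changed. With each library left out in turn, the ranges were 21 to 335 genes changed, 17 to 124 higher, 4 to 211 lower and 20 to 194 by at least 2-fold. They were 10 to 15 lists called. Stim1 passed in every setting, with log2 fold changes from -1.86 to -1.63. Stim2 ranged from -1.32 to -0.96 (adjusted p from 2.42e-10 to 0.126). It missed the threshold at -1.13 with the Xist term, at -1.31 by limma on unfiltered FPKM, and between -1.18 and -0.99 without DKO 1, DKO 3, DKO 4 or WT 3. Over the leave-one-out fits it ran from -1.18 to -0.96. Camera with an estimated correlation called 0 lists and fry 1, against 13. Over the other named genes, 139 values kept their direction but missed the threshold and 3 newly passed. For the lists these numbers were 48 and 14. Depth limits genes near 1 CPM, where 3 libraries hold about 20 counts each.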

Other observations

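The tests of epithelial share, of the mix of layers and of the WT 2 genes, and the splits for higher, lower and 2-fold counts, were chosen after the result was seen. The genes in this paragraph were also picked from their values. A set of genes stood far lower in DKO yet missed the edgeR threshold, with WT 2 between the groups in most of them. With all DKO libraries below all WT libraries, at least 4-fold changes and a mean of at least 50 counts, 20 genes were lower and 5 higher without passing (edgeR adjusted p of the 20 from 0.0519 to 0.103). The iron exporter gene Slc40a1 was the most abundant, at 1813 CPM in WT 1, 2631 in WT 3 and 97.5 in WT 2, against 27.2, 10.8 and 35.7 in DKO 1, 3 and 4. Its log2 fold change was -5.95 (SE 1.15, edgeR adjusted p = 0.0622, and from 2.92e-05 to 0.128 by DESeq2, without a filter, without WT 2, with the replicate block and by limma on FPKM). The transglutaminase gene Tgm3 (log2 fold change -5.15, SE 1.05) had 85.0, 7.56 and 136 CPM in WT 1, 2 and 3 and at most 2.91 in DKO, and the anion exchanger gene Slc26a4 had 17.4, 2.42 and 32.6 CPM and at most 2.03. WT 2 was the lowest WT library for 19 of the 20, DESeq2 called all 20, and 18 were called without WT 2. The pattern was not limited to genes that missed the threshold. Among the 8 largest called falls, WT 2 was also the lowest WT library for Dynap, Kcnmb2, Bglap2, Krt6a, Tmem63c and Syne2. Dynap, for instance, had 32.2, 5.19 and 34.9 CPM in WT 1, 2 and 3. WT 2 was not the lowest for Stim1 or Adora2b. In the other direction, the milk protein gene Csn3 had 61.5 CPM in DKO and a log2 fold change of 2.61 (SE 0.46, edgeR adjusted p = 0.0518).

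A candidate explanation for this set is a stage or region difference in the dissected tissue that also occurs among WT libraries. Genes were therefore picked from 2 WT libraries and compared in DKO with the remaining one. The 32 genes at least 4-fold lower in WT 2 than in WT 1 had a median log2 difference of -3.27 between DKO and WT 3, with 93.8% of them lower in DKO. The 58 genes picked against WT 3 had a median of -0.58 between DKO and WT 1, with 58.6% lower. The genes at least 4-fold higher in WT 2, which such a difference would put higher in DKO, had medians of -1.31 (18 genes) and 0.17 (11 genes), and Spearman's rho across genes, which are not independent replicates, was 0.07 and 0.08. The falls thus carried over for 1 of the 2 choices and the rises by at most 0.17, while -0.58 does not reach the -0.5 that would exclude the explanation, so the dissection and the genotype cannot be told apart for these genes.

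Epithelial keratins were lower while leukocyte and endothelium markers were higher on average in DKO, and the mean log2 difference per library was -0.41 (SE 0.06) for the dental epithelium list, 0.49 (SE 0.23) for leukocytes and 0.37 (SE 0.16) for endothelium. For leukocytes the groups overlapped, with DKO 3 at 0.19 and WT 3 at 0.28 from the WT mean. For endothelium DKO 3 was at 0.26 and WT 3 at 0.21. WT 2 was the lowest library for both lists (-0.31 and -0.25). A lower share of dental epithelium as a whole would take the ameloblast genes down with the keratins. The maturation-stage list, however, lay above the epithelial list by 0.46 (SE 0.10), and 20 of its 24 members lay above the epithelial mean. The directions of both lists were known when this comparison was chosen, so it is not an independent test. The values show only that the maturation-stage list as a whole did not fall with the keratins. A lower share together with a rise of maturation-stage genes within cells would give the same values, so the test cannot exclude that. A different mix of epithelial layers or stages in the dissected tissue stays open beside the genotype, although the WT libraries lay only between -0.04 and 0.03 around their mean for the epithelial list, where the DKO libraries lay between -0.49 and -0.31. The oral keratinocyte list, however, ran from -0.50 in WT 1 to 0.71 in WT 3. The -0.41 of the dental epithelium list was measured over all cells of a library. It could hold a different mix, changes within cells or both, so these cannot be told apart. The most abundant leukocyte and endothelium markers were Cd74 (107 CPM in WT, 127 in DKO) and Eng (74.3 and 102), and 0 of the 16 leukocyte and 1 of the 12 endothelium markers stood in another list.

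Stim1 and Stim2 reads remained in DKO. A mislabelled library is argued against, since the highest DKO library was at 0.594 of the lowest WT library for Stim2, and lower still for Stim1 at 0.396. Cells of other types in the dissected tissue, which may keep both genes, stay open: a DKO library held up to 52.1% of the WT mean. Remaining reads did not track the markers of such cells as predicted: DKO 3 had the most Stim1 (143 CPM) and Stim2 (136 CPM) but the lowest DKO values for mesenchyme (0.12), endothelium (0.26) and leukocyte (0.19) markers, as log2 differences from the WT mean. With 3 DKO libraries this excludes nothing, and gene counts do not separate such cells from transcripts that lack only part of the gene, so these cannot be told apart.

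Among the called genes, those lower in DKO had longer transcripts, with a median of 2325 nt against 1497 nt over all tested genes (permutation p = 0.0017 from 10000 random gene sets). Those higher in DKO had a median of 1861 nt (permutation p = 0.021). The random sets were drawn from all tested genes without matching for abundance or biotype, and treat genes as independent. These p-values therefore do not separate length from what makes a gene easier to call. A length trend between libraries was argued against as the source of the falls themselves. The median log2 fold change of the 45 lower calls was -0.75 before and -0.72 after each library was corrected for its length trend, and 38 of them passed again. Across the tested genes length and log2 fold change had a Spearman rho of only -0.08, so the correction could move these genes little. Whether the lower calls still had longer transcripts after the correction was not tested. Strain DNA flanking the targeted genes was also tested, and 5 of the 153 calls, or 3.27%, lay within 20 Mb of Stim1 or Stim2, both included, against 2.7% of the tested genes (Fisher's exact one-sided p = 0.396).

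Of the called genes that encode no protein, 3 with large falls, chosen after their values were seen, lie beside or inside other genes. RP23-102H7.9 (chromosome 5, 104070064 to 104072325, minus strand) fell 14.4-fold, and the first hypothesis was reads running on from its neighbour Sparcl1. The test was negative, since Sparcl1 had a log2 fold change of -0.43 (SE 0.12) against -3.85 (SE 0.29). The annotation then showed that the gene lies within Gm17660 (104070064 to 104077608, minus strand), and reads of Gm17660, with a log2 fold change of -2.28 (SE 0.47), are a candidate source. Gm17660 was judged by a looser bound than Sparcl1, and its fall was smaller than that of RP23-102H7.9, so shared reads need not account for all of it. Likewise RP24-349N15.4 and RP24-349N15.5, with -2.30 (SE 0.30) and -2.74 (SE 0.28), lie within the metal transporter gene Slc39a8 (chromosome 3, 135825279 to 135888572, plus strand), whose log2 fold change of -1.87 (SE 0.33, edgeR adjusted p = 0.0518) is consistent with shared reads. Gm17660 and Slc39a8 themselves missed the threshold.

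The 6 libraries make 10 splits into 3 and 3, too few for a share below 0.05. The genotype split gave 153 changed genes and the highest other split 5, with DKO 1, WT 1 and WT 2, the Xist-high libraries, against the rest. It gave 108 genes higher and 45 lower, where the larger direction of any other split reached 4, and 87 changed at least 2-fold against 5. In each of these 4 counts 1 of the 10 splits, the genotype split, gave as many. For the gene lists, 2 of the 10 splits called as many as 13, the genotype split and that of DKO 1, DKO 4 and WT 1 against the rest. The remaining splits called from 6 to 12 lists, so this count does not set the genotype split apart.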
